A study of Mus musculus with 2 samples.

How the data were processed

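Total RNA was taken from cultured adipose-derived stromal cells of the inguinal fat pad of mice, with 1 wild-type and 1 Wisp1 knockout sample, each on 1 array. Per the labels' protocols, the cells were grown in DMEM medium with fetal bovine serum, RNA was extracted with TRIZOL and labelled with biotin by the Affymetrix GeneChip WT PLUS kit, and the knockout came from mice with floxed Wisp1 exons 1 to 5 that were crossed to a Cre line. Whether a selection cassette stays in the knockout allele is not clear from the labels. The authors deposited log2 expression values per transcript cluster, made by RMA (background correction, normalization between arrays and summary over probes) with Partek software, per the submitters' processing notes. No version of either, and no list of the arrays that were normalized together, is given in the sources used here, and neither is the genome build of the array design. The log2 scale was read from the values, which ran from 1.88 to 13.62 in wild type and from 1.74 to 13.65 in the knockout, with medians of 3.93 and 3.92. RMA makes the distributions of arrays alike, so a shift of total RNA shared by most genes cannot be seen, and it compresses differences of dim genes. A total of 2938 transcript clusters (4.45%) held exactly the same value on both arrays. The arrays correlated at Pearson r = 0.996 across all 65956 transcript clusters, which are not independent replicates.

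Transcript clusters were named through the platform's gene annotation, which can be old. Exactly 1 gene symbol was listed for 30604 of them, several for 2146, and none for 33206, which are unnamed here rather than without a gene. Symbols were updated through Entrez IDs with the RefSeq gene table of the assembly GRCm38.p6, in which 22818 of the clusters with 1 symbol were found and 827 received a new symbol. That table was used only for names, gene type and gene order (the table order of 831 placed chromosome 15 clusters stepped back to a lower start 4 times), and no coordinates are given because the build of the array design is not known here. Clusters with several symbols were left out. Where a gene had more than 1 cluster (355 of 30142 named genes), the one with the highest mean over both arrays was used.

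Differences were computed as knockout minus wild type on the log2 scale, with no further normalization. With 1 array per group there are no replicates, no test and no p-value, and the precision is limited by the number of arrays. Counts of genes used a 2-fold difference and the 15072 genes whose mean over both arrays was at or above the median of named genes, 4.65. The named genes were fixed by rule: Wisp1 and the other CCN genes, the 15 highest and 15 lowest genes that passed this filter (leaving out predicted or uncharacterised genes, pseudogenes, microRNAs and small RNAs, olfactory, vomeronasal and taste receptors, and immunoglobulin or T cell receptor segments), and in each gene list the members with a 2-fold difference and at least the 2 with the largest difference. This gave 111 genes. A further 60 genes named in the text, such as Sox9, Col1a1 and Gm2895, lie outside the rule and were chosen after their values were seen. A few other list members named beside their lists were likewise chosen after their values were seen.

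A set of 46 gene lists was written from general knowledge of the tissue and the question. They covered the CCN family, cartilage, bone, tendon and mineralization, signalling pathways, matrix, contraction, fat, proliferation, immunity, stress, metabolism, position and sex, the neighbours of Wisp1, and 11 other cell types. Of 1045 list entries 933 matched a named gene, and some genes are on more than 1 list. Each list was summarised by the median difference of all measured members, dim ones included, and by the percentile of that median among 10000 random lists of the same size drawn from genes in the same of 20 bins of mean expression. A list stood apart below percentile 2.5 or above 97.5. The groups, the lists, the naming rule, the comparisons and the other settings were fixed before the data were examined. The alternatives were no filter or a filter on the brighter array, centring on the median, quantile normalization, loess centring on mean expression (span 0.3), the mean over clusters of a gene, clusters with several symbols kept, other fold sizes, 10 bins or no matching, and the mean of a list. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.

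The procedure was tested on simulated data, made by shuffling the differences among genes of like mean expression. The shuffle removes any shared variation of genes. The simulated lists held only genes at or above the median level and were placed among fewer random lists. The rates below therefore do not carry over to lists whose genes vary together, that hold dim genes or that differ in size. For the gene list medians, run on 30142 genes, 3.5% of 200 lists of 30 genes stood apart with no shift added, 95% with a shift of 0.1 and 100% with shifts of 0.2 and 0.3. For the count of genes at least 2-fold higher, run on 15072 genes, 3.5% of 200 genes were called with an added 1.5-fold change, 59.5% with 2-fold, 99% with 3-fold and 100% with 4-fold.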

Results

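RNA from adipose-derived stromal cells, the fibroblast-like progenitor cells that grow out of fat tissue in culture, was measured on 1 expression array per genotype. The cells came from the inguinal fat pad of C57BL/6J mice aged 6 to 10 weeks, either wild type or with a global knockout of Wisp1. Wisp1, now named Ccn4, encodes a secreted matricellular protein of the CCN family that is induced by Wnt signalling. The study concerned its part in cartilage formation during heterotopic ossification, the growth of bone in soft tissue, and the comparison of knockout with wild-type cells asked which transcripts differed when the gene was missing. Each array gave log2 expression values for 65956 transcript clusters, with a median of 3.93 in wild type and 3.92 in the knockout and a highest value of 13.62 and 13.65. There were no replicates, so no difference below could be set against a replicate spread and no p-value was computed. Every difference is the knockout value minus the wild-type value on the log2 scale, and it compares these 2 arrays rather than the genotypes.

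Wisp1 (Ccn4) was at 7.79 in the wild-type array and at 5.40 in the knockout array, a difference of -2.39, or 5.25-fold lower. Only 1 of the 30142 named genes had a lower difference. Per the labels the deletion covers exons 1 to 5, and whether every probe of this gene lies inside it was not analysed here. Of the other CCN genes, Ccn3 (Nov), a family member also found in cartilage, was 0.72 higher, from 8.07 to 8.78. The abundant members Ccn1 (Cyr61, 11.42 to 11.33) and Ccn2 (Ctgf, 10.96 to 10.84) differed by -0.09 and -0.13. Ccn5 (Wisp2) differed by 0.02, a sign that flipped to -0.02 under quantile normalization and under loess centring, and Ccn6 (Wisp3) was dim on both arrays, at 3.75 and 3.72. The median over the 6 CCN genes was -0.06, inside the range of random lists of the same size and level.

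**Figure D1:**
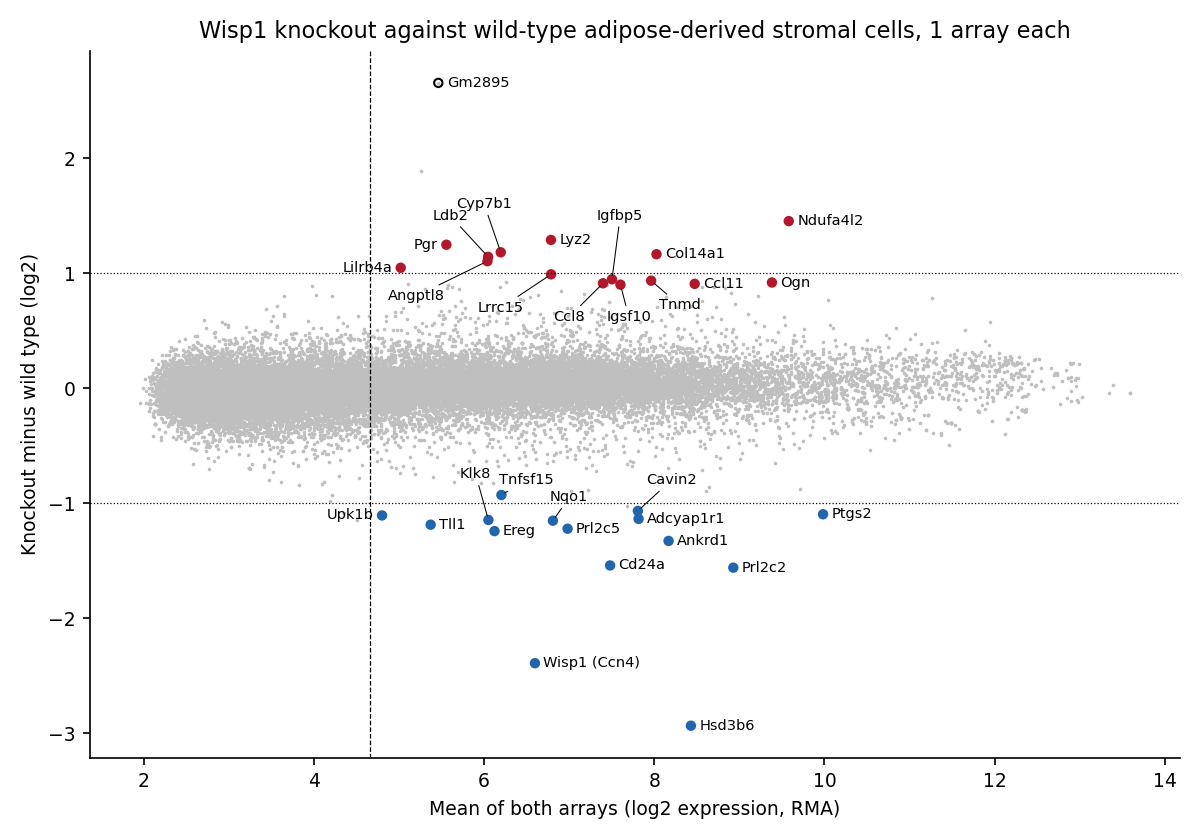
Each point is 1 named gene, with its mean log2 expression over both arrays on the horizontal axis and the knockout minus wild-type difference in log2 units on the vertical axis; filled red and blue points are the 15 highest and 15 lowest genes under the naming rule, the open circle is Gm2895, the dotted lines mark a 2-fold difference and the dashed line marks the filter on dim genes at 4.65. Most genes lie close to 0, with Hsd3b6 and Wisp1 (Ccn4) far below and Gm2895 far above.

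Few transcripts differed by a large amount. Of the 15072 named genes at or above the median level, 10 were at least 2-fold higher and 15 at least 2-fold lower in the knockout array, together 0.166%. The lowest value belonged to Hsd3b6, a hydroxysteroid dehydrogenase of steroid hormone synthesis, at 9.90 in wild type and 6.96 in the knockout (-2.94). Its relatives Hsd3b1, Hsd3b2 and Hsd3b3 were dim, between 3.31 and 3.83, with differences of -0.22, -0.38 and -0.51. Prl2c2 and Prl2c5, proliferin genes of the prolactin family, differed by -1.56 and -1.22, and as near-identical copies they are uncertain as separate measurements. Cd24a, a surface protein used to mark adipocyte progenitors, went from 8.25 to 6.71 (-1.54). Ptgs2, the inducible prostaglandin synthase, went from 10.53 to 9.43 (-1.10).

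The other genes lower by at least 2-fold had varied functions. Ankrd1, a mechanically regulated target of the YAP coactivator, differed by -1.33, and Ereg, which encodes the growth factor epiregulin, by -1.24. A second, dimmer transcript cluster of Ereg differed less, and the mean of both was -0.77. Tll1, a tolloid protease that processes procollagen and the BMP antagonist chordin, differed by -1.19, and Nqo1, a quinone reductase controlled by the transcription factor NRF2, by -1.15. The serine protease gene Klk8 (-1.15), the PACAP receptor gene Adcyap1r1 (-1.14), the uroplakin gene Upk1b (-1.11) and Cavin2 (-1.07), which encodes a coat protein of caveolae, completed the named set, and Tnfsf15, a TNF family ligand, stood just short of it at -0.93. The predicted gene Gm7040, outside the naming rule and named after its value was seen, differed by -1.03.

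Among genes higher in the knockout array, Ndufa4l2, a mitochondrial protein gene induced by low oxygen, went from 8.85 to 10.31 (1.45). Lyz2, the lysozyme of macrophages, went from 6.14 to 7.43 (1.29). The progesterone receptor gene Pgr (1.25), the oxysterol hydroxylase gene Cyp7b1 (1.18) and Ldb2, a cofactor of LIM domain proteins (1.14), were also over 2-fold higher. So were Col14a1, a collagen associated with fibrils (1.16), Angptl8, a secreted regulator of lipoprotein lipase (1.10), and Lilrb4a, an inhibitory receptor of myeloid cells (1.05). Just below 2-fold stood Lrrc15, a membrane protein of activated fibroblasts (0.99), Igfbp5 (0.95), the tendon gene Tnmd (0.93), the small proteoglycan gene Ogn (0.92), the chemokine genes Ccl8 (0.91) and Ccl11 (0.91), and Igsf10 (0.90). Of 2 predicted genes outside the naming rule, named after their values were seen, Gm2895 had the highest difference of all (4.13 to 6.79, 2.65) and Gm12248 the next (4.32 to 6.21, 1.89).

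Gene groups gave a broader picture than single genes. For each of 46 lists of genes, the median difference was placed among 10000 random lists of the same size and expression level, and a list was said to stand apart when it lay outside their central 95%. Of these lists 10 stood apart as higher and 9 as lower, where 2.3 would be counted by chance if genes varied independently. Genes of one pathway vary together, so the placement describes these 2 arrays only.

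**Figure D2:**
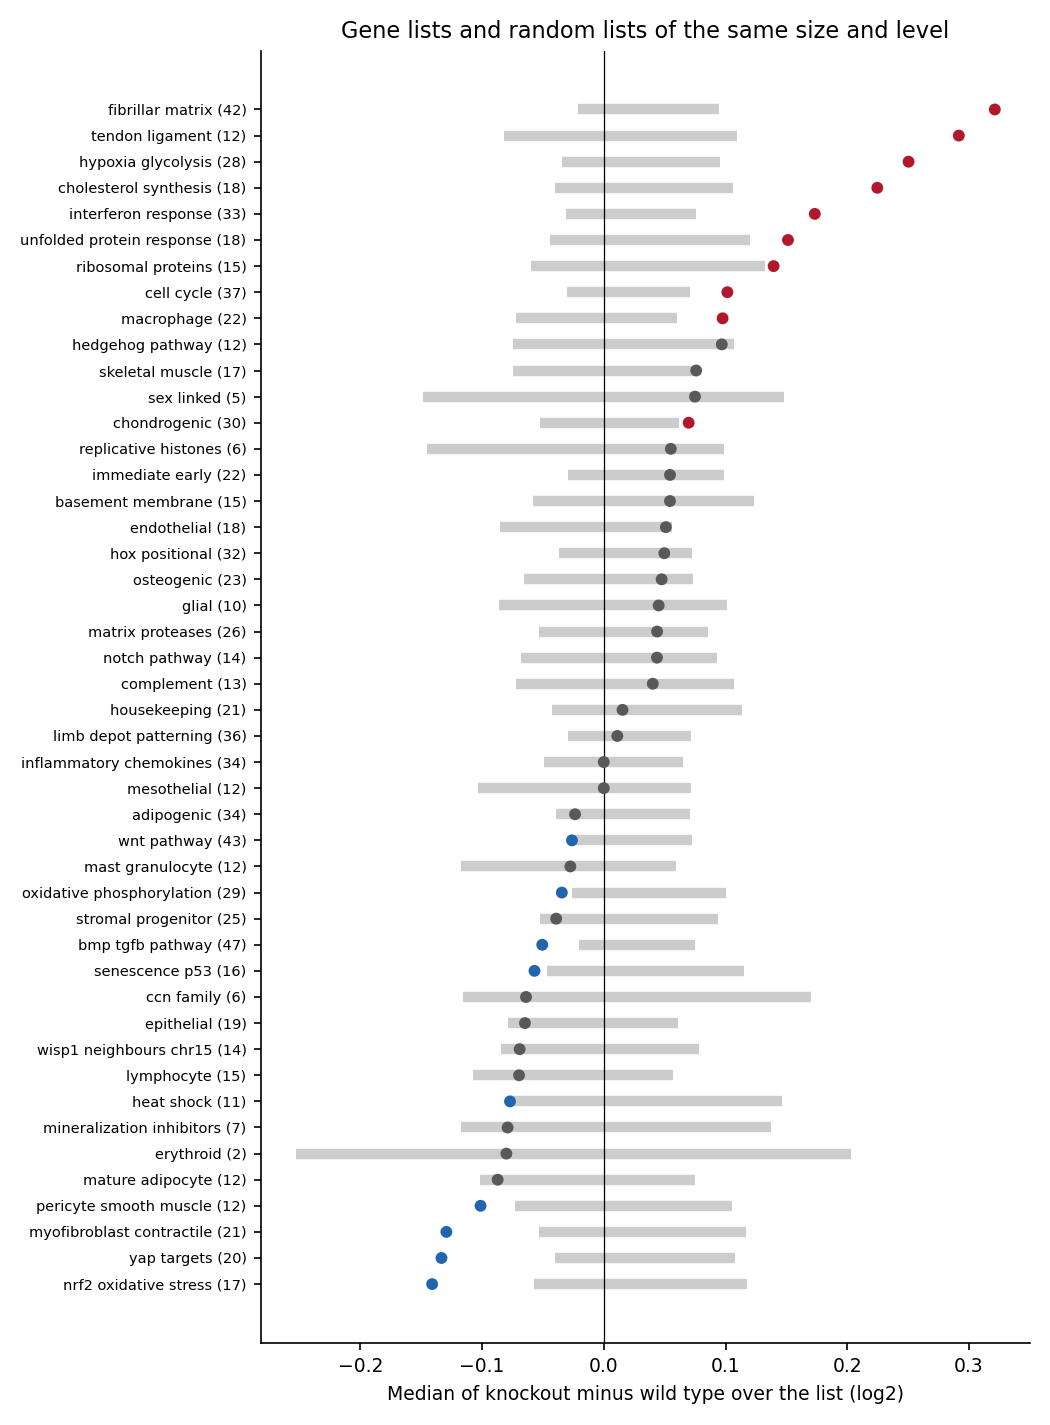
Each point is the median knockout minus wild-type difference over 1 gene list, in log2 units, with the number of measured genes in parentheses; the grey bar is the central 95% of 10000 random lists of the same size and level, and red and blue points lie above and below it. The fibrillar matrix list, at a median of 0.32, lies above its bar and the YAP target list, at -0.13, below its bar.

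Cartilage genes were slightly higher in the knockout array. Of 30 measured chondrogenic genes 22 were higher and 7 lower, with a median of 0.07 (percentile 98.8, random lists from -0.05 to 0.06). None reached 2-fold. Col11a1, a minor fibrillar collagen of cartilage, went from 6.82 to 7.28 (0.46) and Cilp from 4.94 to 5.31 (0.38). Sox9, the transcription factor that directs cartilage differentiation, went from 8.56 to 8.94 (0.37). The main cartilage matrix genes Col2a1 (0.18) and Acan (0.12) and the hypertrophy collagen gene Col10a1 (0.02) differed less, and Acan and Col10a1 were dim on both arrays. Prg4, the lubricin gene, was the lowest member at -0.16.

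Bone genes did not stand apart. Of 23 osteogenic genes 14 were higher and 9 lower, with a median of 0.05 (percentile 88.4). The median was 0.02 under quantile normalization and 0.01 under loess centring, while with the mean of its members, 0.12 (percentile 99.9), the list did stand apart. Ogn, Omd (0.55), Col1a2 (0.52) and Col1a1 (0.50) were the highest members, while Alpl, Sp7 and Bglap, which mark osteoblasts, differed by 0.09, 0.10 and -0.18. The 7 inhibitors of mineralization had a median of -0.08 (percentile 8.28), with Tnfrsf11b, the decoy receptor osteoprotegerin, at -0.61, Mgp at -0.37 and Fbln1 at 0.39, and they stood apart as lower over members at or above the median level (-0.17, percentile 1.14) and with clusters of several symbols kept (-0.11, percentile 1.86). Tendon and ligament genes did stand apart: 10 of 12 were higher, the median was 0.29, and none of the random lists reached it. Col14a1 and Tnmd led that list, and 4 of its other members were higher by 0.34 to 0.38, among them Kera, which was dim on both arrays (2.41 to 2.75). The transcription factor genes Scx (0.09) and Mkx (-0.03, dim) differed little. Without the members that the tendon list shares with the fibrillar matrix list its median was 0.17 (percentile 99.8), a setting chosen after seeing the data.

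Genes of the collagen-rich matrix differed together. Of 42 fibrillar matrix genes 36 were higher and 6 lower, with a median of 0.32 that no random list reached, and 14 lay above the central 95% of single genes of their level. Besides Col14a1, the largest differences were in the elastic fibre gene Fbn2 (0.82), the proteoglycan gene Vcan (0.80), the matricellular gene Thbs2 (0.78) and the collagen lysyl hydroxylase gene Plod2 (0.62). The abundant collagen genes Col1a1, Col1a2 and Col3a1 were higher by 0.50, 0.52 and 0.43 and Postn by 0.57, while Tnxb was lower (-0.45). Basement membrane genes did not move with them, with 9 of 15 higher and a median of 0.05 (percentile 66.5). Nor did proteases of the matrix and their inhibitors, with 14 of 26 higher and a median of 0.04 (percentile 76.6), although Mmp11 was 0.88 higher and Mmp3 was lower (-0.68).

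Signalling lists went in several directions. Of 20 targets of YAP 19 were lower, with a median of -0.13 that every random list exceeded, led by Ankrd1 and Crim1 (-0.86), and the mean was -0.22. The BMP and TGF-beta list also stood apart as lower, with a median of -0.05 (percentile 0.10), although its members were split, 22 higher and 25 lower, and the median ranged from -0.09 to -0.02 over the alternative settings. Its lower members included the secreted antagonists Grem1 (10.15 to 9.27, -0.88) and Fst (-0.62), and its higher members the TGF-beta-induced matrix gene Tgfbi (0.83) and the activin receptor gene Acvr2a (0.71). The Wnt list, with 18 genes higher and 25 lower, had a median of -0.03 (percentile 2.03) and a mean of 0.03, so its sign depended on the summary. Lgr5 (0.75) and Lgr4 (0.66), receptors for R-spondins, were its highest members and the Wnt antagonist Sfrp4 its lowest (-0.66). Hedgehog genes had a median of 0.10 (percentile 96.1), with Cdon at 0.56 and the target gene Ptch1 at 0.41, while Gli1 (-0.11) and Hhip (-0.26), both dim, were lower. Notch genes had a median of 0.04 (percentile 77.3), with Notch3 at -0.31 and Hey1 at 0.18. Neither list stood apart, except the hedgehog list when random lists were not matched on level (percentile 98.02).

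**Figure D3:**
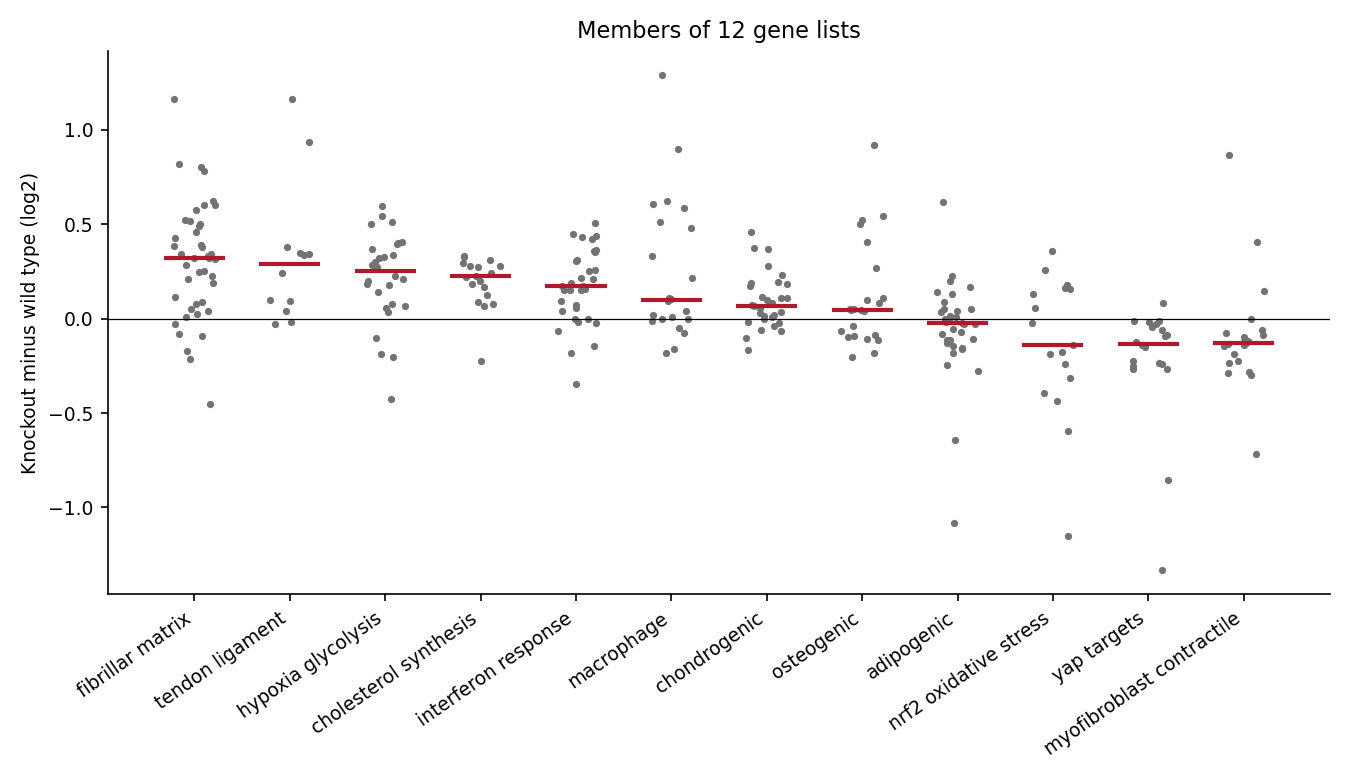
Each grey point is 1 gene of the list named below it, at its knockout minus wild-type difference in log2 units, and each red line is the median of the list; the sideways spread of the points has no meaning. Most fibrillar matrix and cholesterol synthesis genes lie above 0 and most YAP target and contractile genes below it, while the macrophage list has a few genes far above 0.

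Contractile genes were lower. Of 21 myofibroblast and contractile genes 17 were lower and 3 higher, with a median of -0.13 that every random list exceeded. Vcl (-0.30), Tpm2 (-0.29) and the smooth muscle actin gene Acta2 (-0.13) were among the lower members, together with the integrin gene Itga8 (-0.72), while Itga11, a collagen-binding integrin, was 0.87 higher. Markers of pericytes and smooth muscle also stood apart as lower, with a median of -0.10 over 12 genes (percentile 0.71), of which 7 were lower and 5 higher, and with lower values of Mcam (-0.69), Myh11 (-0.51) and Cspg4 (-0.36). Ndufa4l2 was the highest member of that list, and with the mean in place of the median the list no longer stood apart (-0.0050).

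Genes of fat differentiation differed little. The adipogenic list had a median of -0.02 over 34 genes (percentile 7.06), with 13 higher and 20 lower. Its regulators Pparg (0.20) and Cebpa (-0.28) went opposite ways, and the lipid-binding gene Fabp4 differed by -0.11. Markers of mature adipocytes had a median of -0.09 over 12 genes (percentile 4.80), with lower values of the hormone genes Retn (4.90 to 3.81, -1.08) and Adipoq (4.50 to 3.86, -0.64), both dim on the mean of the arrays. Stromal progenitor markers had a median of -0.04 over 25 genes (percentile 4.72), with Cd24a and Dlk1 (-0.58) lowest. None of these lists stood apart on its median, but all did so as lower with the mean of members (-0.06, -0.19 and -0.13 in the order given), the adipogenic list also under loess centring and the stromal progenitor list also over members at or above the median level.

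Immune genes differed by kind. The macrophage list stood apart as higher, with 15 of 22 genes higher, 5 lower and a median of 0.10 (percentile 99.9), which was 0.51 over members at or above the median level. After Lyz2 the largest differences were in the Fc receptor chain gene Fcer1g (5.13 to 6.02, 0.90), Ctss (0.63), Lyz1 (0.61), which is nearly identical to Lyz2, Cd68 (0.58) and Tyrobp (0.51). The macrophage receptor genes Csf1r (0.01) and Adgre1 (-0.08) were dim and differed little. The interferon response stood apart as well, with 25 of 33 genes higher and a median of 0.17 that no random list reached, including Iigp1 (0.50), Oasl2 (0.45) and Mx2 (0.44), while Ifit2 was lower (-0.35). Inflammatory genes and chemokines had a median of 0 over 34 genes (percentile 38.5), with Ccl8 and Ptgs2 at the ends. Complement genes had a median of 0.04 over 13 (percentile 69.6, and a median just below 0 under quantile normalization), with C4b at 0.55 and Cd55 at -0.37. Lymphocyte markers (15 genes, median -0.07, percentile 13.2, Cd79a at 0.28 and Ms4a1 at -0.25) and mast cell and granulocyte markers (12 genes, median -0.03, percentile 51.8, Csf3r at -0.12 and Mpo at -0.07) did not stand apart.

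Genes of metabolism and cell stress gave some of the clearest shifts. Of 28 hypoxia and glycolysis genes 24 were higher, with a median of 0.25 that no random list reached, led by Bnip3 (0.60), Egln3 (0.55), Egln1 (0.51) and Pdk1 (0.50). Its lower members were Ndrg1 (-0.43), Car12 (-0.20, dim), Adm (-0.19) and Pfkfb4 (-0.10). Of 18 cholesterol synthesis genes 17 were higher, with a median of 0.22 that no random list reached, led by Idi1 (0.33), Cyp51 (0.33), Lss (0.31) and Hmgcs1 (0.30). The unfolded protein response list had a median of 0.15 over 18 genes (percentile 99.6), with the stress genes Trib3 (0.79) and Chac1 (0.65) highest. Not all of its members followed: Hsp90b1 (0), Calr (0.01) and Edem1 (0.03) differed little, and Sdf2l1 was lower (-0.19). All 15 ribosomal protein genes were higher, with a median of 0.14 (percentile 98.1), by as much as 0.27 for Rpl10a and 0.20 for Rps24. In the other direction, the NRF2 oxidative stress list had a median of -0.14 over 17 genes (percentile 0.02), with 10 lower and 7 higher. Nqo1, Gsta4 (-0.60), Gclc (-0.43) and Hmox1 (-0.39) were lowest and Gpx3 (0.36) and Mt2 (0.26) highest, and the median was -0.081 over members at or above the median level. Oxidative phosphorylation genes had a median of -0.03 over 29 (percentile 1.38), with Ndufa4 at -0.32 and Ndufb3 at -0.28, and heat shock genes a median of -0.08 over 11 (percentile 2.17), with Hspb1 at -0.39 and Hsph1 at -0.37. The small lower shifts of those last lists did not stand apart under every alternative setting.

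Proliferation genes were modestly higher. Of 37 cell cycle genes 30 were higher and 5 lower, with a median of 0.10 (percentile 99.9) that was 0.07 under quantile normalization, and the mitotic genes Ccnb2 (0.52) and Mki67 (0.47) were highest. Senescence and p53 target genes had a median of -0.06 over 16 (percentile 1.34), with Mdm2 at -0.33 and Plk2 at 0.42, and did not stand apart with the mean of members or with unmatched random lists. Replicative histone genes (6 genes, median 0.06, percentile 89.7, H4c1 at -0.23 and H3c8 at 0.16) and immediate early genes (22 genes, median 0.05, percentile 69.6, Egr1 at 0.63 and Nr4a3 at -0.54) did not stand apart, except the histone genes as higher when clusters of several symbols were kept (0.13, percentile 99.6).

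Lists of position and identity genes did not stand apart on their medians. Hox genes had a median of 0.05 over 32 (percentile 86.1), with Hoxc10 (0.58) and Hoxc12 (0.54) highest, and stood apart as higher with the mean of members (0.08, percentile 98.7). Hoxc8 to Hoxc13, a block picked after the values were seen, were all higher, by 0.22 to 0.58. In contrast, Hoxc5 (-0.01) and Hoxc6 (0.01) differed little, and Hoxd8 was the lowest Hox gene (-0.25). Limb and fat depot patterning genes had a median of 0.01 over 36 (percentile 41.8), with Six2 at -0.54 and Meox1 at 0.48. The Y-linked genes Eif2s3y (6.01 and 6.16), Uty (6.16 and 6.28) and Kdm5d (5.55 and 5.63) had signal on both arrays and Xist, the RNA that coats the inactive X chromosome, was dim on both (3.25 and 3.18), so the cultures did not differ in these sex markers. The median over the 5 sex-linked genes was 0.07 (percentile 84.4), with Tsix at -0.15. Housekeeping genes had a median of 0.02 over 21 (percentile 31.3), a sign that flipped to -0.01 under quantile normalization and -0.02 under loess centring, with Pgk1 at 0.40 and Polr2a at 0.27.

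Markers of the remaining cell types that fat tissue can hold did not stand apart on their medians, although several did under other settings. The median was 0.05 over 18 endothelial genes (percentile 96.7), where Cdh5 (3.81 to 4.62) and Emcn (3.24 to 4.04) were each 0.80 higher at low levels, and 0.08 over 17 skeletal muscle genes (percentile 97.45, just inside the limit), with Tnnt3 at 0.46 and Chrna1 at 0.42. The skeletal muscle list stood apart as higher under quantile normalization (0.10), loess centring (0.10), over members at or above the median level (0.17) and with the mean of members (0.15), and the endothelial list with the mean of members (0.09). Epithelial genes had a median of -0.06 over 19 (percentile 7.53), with Krt18 at -0.35 and Krt7 at 0.20, and mesothelial genes 0 over 12 (percentile 64.2), with Upk1b and Nkain4 (-0.34) lowest. Glial genes had a median of 0.05 over 10 (percentile 78.5), with Ncam1 at 0.62 and Scn7a at 0.51. Over members at or above the median level and with the mean of members, the glial list stood apart as higher (0.25 and 0.13) and the mesothelial list as lower (-0.22 and -0.12). Of the erythroid markers only 2 were measured, Slc4a1 (-0.16) and Alas2 (0), with a median of -0.08 (percentile 25.5).

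Genes around Wisp1 on chromosome 15 were looked at because a targeted deletion can alter its surroundings. The 14 named neighbours had a median of -0.07 (percentile 5.55) and did not stand apart, with the next gene, Ndrg1, at -0.43 and Khdrbs3 at -0.18. The 6 neighbours at or above the median level did stand apart as lower (-0.11, percentile 0.89). Gm2895, a long noncoding RNA gene that comes after Ndrg1 in gene order, where it was placed by its symbol alone, was 6.30-fold higher. It lay between 2 transcript clusters with no gene listed, which were also higher, from 5.43 to 6.42 (1.00) and from 3.94 to 6.44 (2.498). The 3 clusters followed directly after that of Wisp1 in table order, which passes along the chromosome more than 1 time and holds Ndrg1 in a later pass.

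**Figure D4:**
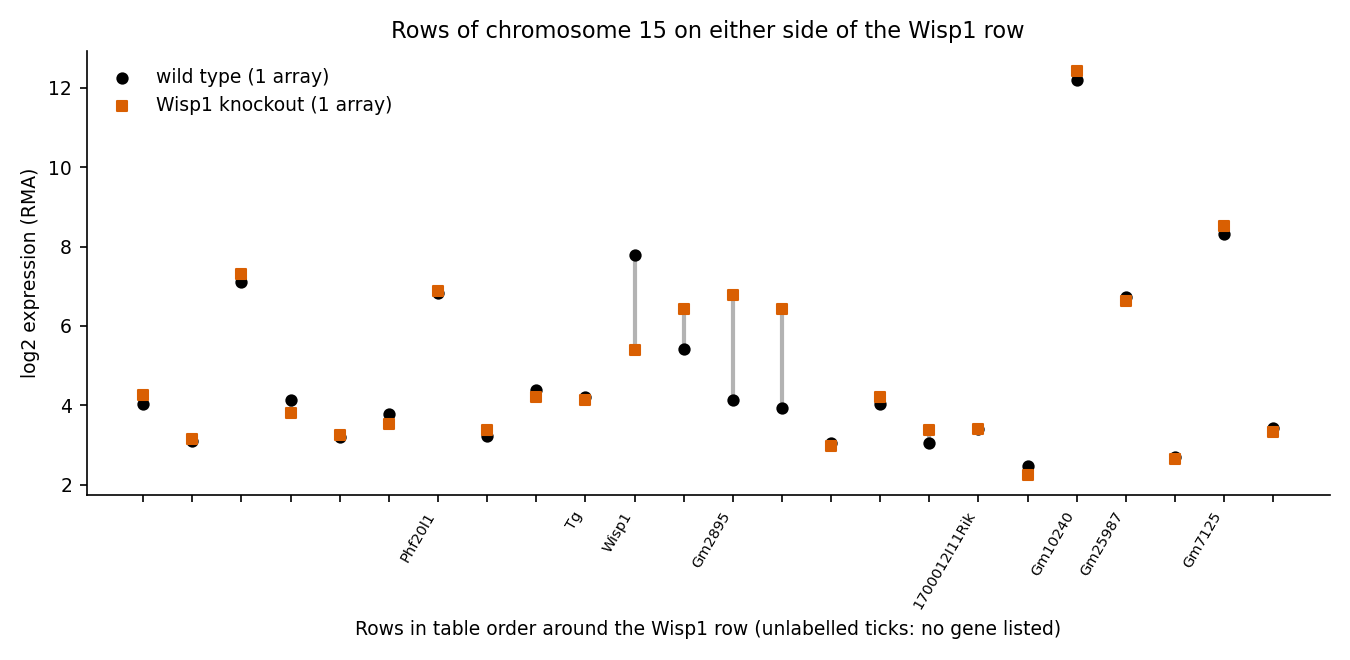
The log2 expression of the transcript clusters on either side of Wisp1 on chromosome 15, in table order, is shown with black circles for wild type and orange squares for the knockout (1 array each), joined by a grey line; unnamed positions have no gene listed. The Wisp1 value is lower in the knockout and the next 3 values are higher, while those farther away lie close together.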

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

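The tests of explanations in this part were chosen after the result was seen, although the list medians, their percentiles and the loess centring they draw on were planned. Transcript clusters with no gene listed entered no gene count or gene list above, where only those around Wisp1 were shown, and 34 of all such clusters were at least 2-fold higher and 20 at least 2-fold lower in the knockout array. A run of 9 clusters, neighbours in table order, on chromosome 9, none with a gene listed, was higher with a median difference of 1.30 (0.71 to 1.39). A run of 3 neighbouring clusters on chromosome 15, next after Wisp1 in table order, was higher with a median of 2.498. Runs of 3 or more neighbouring clusters, each at least 1.5-fold higher, were counted when at least 1 cluster had no gene listed. Of 15 such runs these were the only 2 with a median of at least 2-fold higher, against 2 runs that were lower by the same rule. No cause was tested for the run on chromosome 9.

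The 3 clusters after Wisp1 include Gm2895, a long noncoding RNA gene. Scatter of dim signals, which would go both ways, could not be decided. Of 8874 windows of 3 neighbouring clusters within 0.5 of their level 0 were lower by as much, the lowest at -1.55. A window median that low needs 2 such clusters, and Wisp1 at -2.39 already ranked 2 from the lowest over all clusters. So 0 was the only possible count, and the 3 clusters were picked because they were high. A shift of the whole region is argued against, with a median of 0.032 (-0.34 to 0.33) over the 10 clusters before Wisp1 and 10 after the third in table order. Transcription that runs on past the deleted exons could raise them but stays open: 0 of the 3 clusters before Wisp1 were 2-fold higher (-0.18 to 0.14), which any effect downstream of the deletion would give. Ndrg1, which lies between Wisp1 and Gm2895 in gene order, was lower (-0.43). Its cluster sits in a later pass of the table order than those of Wisp1 and Gm2895. Strands were not analysed, so the Ndrg1 value cannot decide the question. Another effect of the altered allele, such as a selection cassette, whose presence is not clear from the labels, also remains open.

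The macrophage list was higher in the knockout array. Its percentile of 99.9 among random lists matched on level is the observation itself, so scatter of dim genes was not tested separately. More macrophage RNA in the knockout culture may account for it but is not established: of the 8 members at or above the median level in the wild-type array 7 (87.5%) were higher, with a median of 0.53, against 0.013 over the 14 dimmer members, in a list picked because it was higher. Lyz2 (6.14 to 7.43), Lyz1, which is nearly identical to it, and Cd68 (5.77 to 6.35) had the highest levels. Of the dimmer members Csf1r (0.01) and Adgre1 (-0.08) did not follow them, while Ctss (0.63) and Tyrobp (0.51) were higher. Among the brighter members, Cd14 was lower (-0.18). An effect of the genotype within the stromal cells stays open as untested, and no sort that would remove macrophages is named in the labels.

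The fibrillar matrix list was higher in the knockout array. A trend of the difference with mean expression as the whole cause is argued against, since the list median was 0.28 after loess centring against 0.32 before. A different state of the cultures, such as density or oxygen supply, could also move these genes, and the hypoxia and glycolysis list had a median of 0.25. With 1 culture per genotype, the state of the culture and the genotype cannot be told apart. The loss of Wisp1 itself stays among the open explanations, as untested.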

How the results depend on the processing

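The alternatives without the Gm genes and with members of a list left out were chosen after seeing the data, and the others were planned. The Wisp1 difference lay between -2.38 and -2.43 under median centring, quantile normalization, loess centring and the mean over clusters of a gene. As Wisp1 has a single cluster, the last of these could not change it. The count of genes at least 2-fold higher lay between 8 and 11 and that of lower genes between 14 and 17 under all settings that kept the fold size. At 1.5-fold the counts were 108 higher and 70 lower, and at 3-fold 2 and 2, as other thresholds must give. The chondrogenic median lay between 0.06 and 0.10 and stood apart in 9 of 9 alternatives. Median centring, counted among the alternatives here and below, shifts all genes alike and could not change whether a list stood apart. The number of lists that stood apart was 19 in 5 alternatives, not always the same lists: quantile normalization lost the Wnt list and gained the skeletal muscle list, and loess centring lost the heat shock and Wnt lists and gained the adipogenic and skeletal muscle lists. It was 21 with clusters of several symbols kept, 24 over members at or above the median level, 16 with no matching and 25 with the mean of members. With the mean of members 10 lists newly stood apart, among them the osteogenic (0.12) and CCN (-0.32) lists, the last of which holds Wisp1 itself. Over members at or above the median level 6 lists did, the glial, mesothelial, mineralization inhibitor, skeletal muscle, stromal progenitor and Wisp1 neighbour lists. The Wnt list reversed with the mean of members, at 0.034 (percentile 68.3), and stood apart in 4 of 9 alternatives, and the cause was not tested. The senescence, heat shock and oxidative phosphorylation lists stood apart in 7 of 9 and the pericyte list in 8 of 9. Of 170 single genes other than Wisp1, Lrrc15 passed 2-fold at 1.00 under median centring and Ereg no longer did at -0.77 with the mean over clusters. None reversed as a called value, but that says little. A reversal would need a gene to go from 2-fold higher to 2-fold lower or back, while the loess trend spanned only -0.037 to 0.051. Signs of small differences were not part of that call, and that of Ccn5 did flip. Leaving out the members that the tendon list shares with the matrix list, Ndrg1, Lyz1 and Lyz2, or the members the Wnt list shares with others changed none of the 4 calls concerned. Dim genes, such as Cdh5, have differences that RMA can compress, and no replicate bounds their noise.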

Other observations

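All observations in this part were made after the data were seen. The families use named genes at or above the median level, and the signs of the medians of the families that stood apart held under median centring, quantile normalization and loess centring, although sizes moved. Several families of small noncoding RNAs had lower medians in the knockout array. Of 38 genes whose symbol starts with Snord, small nucleolar RNAs that guide methylation of ribosomal RNA, 35 were lower and 2 higher, with a median of -0.25 that every matched random list exceeded, for example Snord61 (9.78 to 9.25) and Snord8 (8.50 to 7.98). The 14 Snora genes, 9 lower and 5 higher, had a median of -0.13 (percentile 0.04), and of 14 spliceosomal RNA genes starting with Rnu 13 were lower, with a median of -0.11 (percentile 0.22), such as Rnu1a1 (11.64 to 11.34). The largest such family, 209 microRNA genes starting with Mir, was more evenly split, with 119 lower, 89 higher and a small median of -0.03, although every matched random list exceeded it. No cause was tested.

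In the same scan of 139 families of at least 10 genes by the start of their symbols, 9 stood apart as higher and 10 as lower. By chance 6.95 would be counted if genes varied independently, and genes of one family can vary together. Parp genes, several of which respond to interferon, were higher in 9 of 11 cases, with a median of 0.22 that no random list reached, including Parp4 (0.27), Parp12 (0.27) and Parp14 (0.22). Genes starting with Rpl (125 of 145 higher, median 0.12) and Rps (65 of 79 higher, median 0.12) were higher as well. Many of these are pseudogenes, whose probes may also detect the parent genes, and probe sequences were not examined here. Zinc finger genes starting with Zfp had a median of 0.06, with 197 of 277 higher, but of 0.03 under quantile normalization and 0.04 under loess centring. Complex I genes starting with Ndufb had a median of -0.09, with 10 of 11 lower. Genes starting with Ndufa did not stand apart (median -0.02, 6 higher and 8 lower, percentile 8.68), so the lower values do not describe complex I as a whole. Among runs of neighbouring clusters that held at least 1 with no gene listed, several that were higher together included a higher named gene, among them Pgr, Vcan, Fbn2 and Adamts6, and the runs of 3 clusters that were lower, none with a gene listed, lay on chromosome 5 (median -0.97) and on the mitochondrial chromosome (-0.70). The runs were not recomputed under other settings.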
